A study of Homo sapiens with 6 samples.

How the data were processed

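Total RNA was extracted with TRIzol from LX-2 cells, and libraries were made with an Illumina TruSeq RNA kit, per the labels' protocols. The 6 libraries form 2 groups of 3, TGF-β1 with DMSO and TGF-β1 with compound 11 at 10 µM for 48 h, and group and replicate number were taken from the sample labels. The submitters' processing notes name Bowtie 0.12.2 and the builds mm8 and GRCh38.p12 without saying what each was used for; mm8 is a mouse build, and the genes listed are human. The counting tool, the annotation release, the use of strand and any filter are not given in the sources used here.

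The deposited table holds 1 value per gene and library under headers that name FPKM, per the file headers. Each column sums to 1000000 over the genes listed, and values of low genes fall with transcript length, so the deposited values are on the TPM scale and are called TPM here. The authors' scaling to a fixed total keeps no depth, so neither sequencing depth nor counting error can be given. On this scale a gene can fall because others rise; the 20 most abundant genes of each library took 12.3% to 14.0% of its total. Of the 20332 genes, 3800 were listed at 0 in all 6 libraries and 617 had no symbol; 20113 identifiers (98.9%) were found in GENCODE v29, which supplied GRCh38 coordinates, gene types, transcript length and GC content. The genes are almost all protein-coding, so the list of nuclear-retained and structural RNAs had 0 tested members. No pair of libraries shared more than 8 identical values among tested genes, so none was a copy of another.

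Values were transformed as log2(TPM + 1). The 12067 genes with at least 1 TPM in at least 3 of the 6 libraries were tested with limma 3.58.1 in R 4.3.3, as a linear model on group with moderated variances following a mean trend, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Because the values are not counts, no count model was used. The design had assumed FPKM; the same test was applied to the TPM values. Fold changes from the model are on the log2(TPM + 1) scale, which understates changes of low genes; folds given without log2 are ratios of mean TPM. SEs are those of limma.

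Before the data were examined, 45 gene lists were fixed, and the 42 with at least 5 tested members were tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over lists; camera with an estimated correlation and fry were run beside it. Counts of members past the threshold are given over all genes tested and adjusted over the list alone. The rule for named genes was fixed at the same time. It takes the 12 highest and 12 lowest log2 fold changes among genes past the threshold with a symbol, a mean of at least 5 TPM in the higher group and no overlap between groups. It adds up to 4 members with the smallest adjusted p from each list past camera's threshold or with at least 3 members past the gene threshold, and 17 fixed genes of fibrosis and PI3K-AKT signalling. The rule gave 180 genes, of which a part is named in the text; some of them are not reported here.

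The pipeline was tested on simulated data made from the levels and spread of the same 12067 genes with 200 changed. It recovered 34% of the genes changed 1.25-fold, 78% of those changed 1.5-fold, 98% of those changed 2-fold and 100% of those changed 4-fold, with 3.73% of its calls on unchanged genes. These rates hold for 200 changed genes. In the data 5984 genes passed, so the Benjamini-Hochberg cutoff on the unadjusted p was less strict there. HSPA8, 1.21-fold lower, passed in the data, whereas PIK3R1, 1.16-fold higher, did not. The share of real changes recovered at a given fold is therefore not known, and small differences can still be missed. In a simulation of the 42 lists with 1 changed, camera called that list and 0 others. The simulated genes vary independently, which favours the preset correlation.

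Alternatives fixed beforehand were pseudocounts of 0.1 and 0.01, no filter except on genes at 0 throughout, a filter on a mean of at least 5 TPM, rescaling to the same total or the same upper quartile, quantile normalization, variances without a trend, the replicate number as a block, and each library left out in turn. Chosen after seeing the data were a correction of each library for its trend over GC content and transcript length (loess, span 0.3) and the removal of the 20 genes with the highest mean TPM followed by rescaling. Count-based tools could not be applied.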

Results

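RNA was sequenced from LX-2 cells, an established human hepatic stellate cell line. Stellate cells are the pericytes of the liver sinusoid, and TGF-β1 turns them into matrix-producing, contractile myofibroblasts. All 6 samples were of cells given TGF-β1. In 3 of them it was given with the solvent DMSO, and in the other 3 with compound 11 at 10 µM, for 48 h. The labels name the compound only by its number. The comparison asks how the compound altered the transcriptome of TGF-β1-treated stellate cells; the series title places it among agents against liver fibrosis and names the PI3K-AKT pathway. Cells without TGF-β1 were not analysed here, so no level can be set against resting cells. The table lists 20332 genes, of which 14699 to 14830 per library were above 0. Its values carry no sequencing depth, which is therefore unknown.

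Compound 11 lowered the genes of the contractile, collagen-producing state and raised the collagenase MMP1, many cytokines and NF-κB targets. ACTA2, the smooth muscle actin that marks myofibroblasts, fell from 176 ± 4.47 to 6.28 ± 0.416 TPM (SD, n = 3 per group). COL1A1, the main chain of type I collagen, fell from 1132 ± 30.9 to 102 ± 6.91 TPM. MMP1, interstitial collagenase, rose from 302 ± 11.7 to 11398 ± 262 TPM, and the chemokine CXCL8 from 3.82 ± 0.455 to 158 ± 4.01 TPM. Every one of the 42 mitotic genes on the G2/M list fell. In limma with Benjamini-Hochberg adjustment, 5984 of the 12067 genes tested passed an adjusted p of 0.05, 3052 higher and 2932 lower with compound 11. Of these, 701 also differed by at least 2-fold on the log2(TPM + 1) scale, 410 higher and 291 lower.

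**Figure D1:**
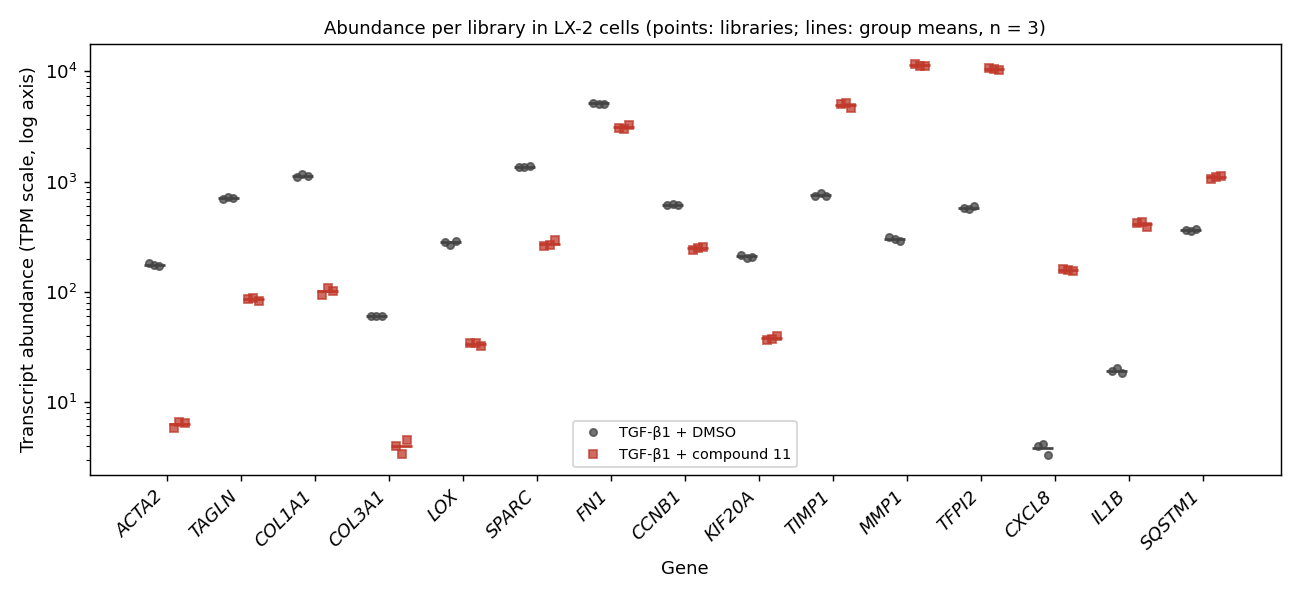
Abundance of 15 genes in each of the 6 libraries, on a log axis in TPM; circles are the 3 DMSO libraries, squares the 3 compound 11 libraries, and short lines the group means. ACTA2 drops from 176 to 6.28 TPM and MMP1 climbs from 302 to 11398 TPM.

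The 3 libraries of each group lay close together. The first principal component of the log2 values held 81.1% of the variance and separated the groups, and the second held 5.97%. Pearson correlations across tested genes, which are not independent replicates, were 0.993 to 0.994 within groups and 0.960 to 0.961 between them. The highest and lowest TPM of the groups did not overlap for 6972 tested genes, 57.8%, where chance gives 10%. The labels do not say whether the replicates were separate cultures, so the p-values measure the spread between these samples, which may be technical.

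Among 15 tested collagen genes, 10 fell and 2 rose, with the same counts adjusted over the list alone. The median log2 fold change was -1.19 (camera adjusted p = 2.67e-05, and adjusted p = 0.135 with an estimated correlation). Fibrillar collagens were among those that fell: COL1A1 was 11.2-fold lower (log2 fold change -3.47 ± 0.05 SE, limma, Benjamini-Hochberg adjusted p = 1.37e-10), COL3A1 went from 60.2 ± 0.256 to 3.95 ± 0.538 TPM, COL5A1 from 236 to 42.6 TPM and COL5A2 from 147 to 48.2 TPM. COL1A2, the partner chain of COL1A1, was far less abundant in these cells and fell from 5.86 to 0.662 TPM. COL1A1 lies on chromosome 17 at 50183289 to 50201632 and COL3A1 on chromosome 2 at 188974320 to 189012746 (GRCh38, GENCODE v29), both protein-coding.

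Genes that process and crosslink collagen fell with it. Of 19 tested, 13 fell and 1 rose, or 15 and 1 adjusted over the list alone (camera adjusted p = 0.000534, and adjusted p = 0.0922 with an estimated correlation). LOX, which crosslinks collagen and elastin, fell from 281 to 33.8 TPM. SERPINH1, the collagen chaperone of the endoplasmic reticulum, was 2.19-fold lower, P4HA2, a prolyl hydroxylase, 1.95-fold lower, and LOXL2 1.72-fold lower. Of 27 matrix glycoproteins and proteoglycans, 18 fell and 5 rose, with the same counts adjusted over the list alone (camera adjusted p = 9.32e-06, and adjusted p = 0.25 with an estimated correlation). TGFBI fell from 2375 to 445 TPM, SPARC from 1362 to 273 TPM and THBS1 from 468 to 80.6 TPM. Fibronectin, FN1, remained among the most abundant transcripts at 5125 TPM in DMSO and 3116 TPM with the compound, a fall of 1.64-fold.

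The contractile genes moved the same way. Of 23 tested, 18 fell and 2 rose, again with the same counts adjusted over the list alone (median log2 fold change -0.75, camera adjusted p = 2.4e-07, and adjusted p = 0.0945 with an estimated correlation). ACTA2 was 28.1-fold lower (log2 fold change -4.61 ± 0.06 SE, limma, Benjamini-Hochberg adjusted p = 1.13e-10); it lies on chromosome 10 at 88935074 to 88991339 (GRCh38, GENCODE v29). TAGLN, an actin-binding protein of smooth muscle, was 8.33-fold lower, MYL9, the regulatory myosin light chain, 3.55-fold lower, and TPM2, a tropomyosin, 1.76-fold lower. ACTG2 fell from 8.56 to 0.135 TPM, although its reads resemble those of ACTA2 and other actins and their division by the authors' counting is not known. Of 18 activation markers of stellate cells, 13 fell and 4 rose, with the same counts adjusted over the list alone (camera adjusted p = 0.000146, and adjusted p = 0.0798 with an estimated correlation). They include PDGFRB, the receptor for the stellate cell mitogen PDGF, which fell from 26.5 to 9.75 TPM. TIMP1, an inhibitor of matrix metalloproteinases and a marker on the same list, went the other way, from 756 ± 23.5 to 4980 ± 289 TPM. FAP, CD44 and VIM on that list also rose (log2 fold changes 1.445, 0.64 and 0.23). Many of the markers that fell, namely ACTA2, COL1A1, TAGLN, LOX, SPARC, FBN1 and LOXL2, are also on the collagen, crosslinking, matrix or contractile lists above. The transcription factor FOXS1 was at 8.29 TPM in DMSO and listed at 0 in all 3 compound 11 libraries. CPA4, a carboxypeptidase, fell from 259 to 7.8 TPM, MEST from 231 to 9.95 TPM, KRT81 from 43.6 to 2.91 TPM and MAP3K7CL from 95.7 to 13.6 TPM. KRT81 shares sequence with other hair keratins, so its level is uncertain.

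Among 23 matrix proteases and inhibitors, 11 rose and 7 fell (11 and 8 adjusted over the list alone), and the list as a whole did not pass camera's test (adjusted p = 0.173, and adjusted p = 0.308 with an estimated correlation), although it did with no filter (adjusted p = 0.0342). MMP1 was 37.7-fold higher (log2 fold change 5.23 ± 0.03 SE, limma, Benjamini-Hochberg adjusted p = 8.97e-13); it lies on chromosome 11 at 102789920 to 102798160 (GRCh38, GENCODE v29). MMP3, stromelysin, rose from 1.87 to 122 TPM, MMP9, a gelatinase, from 0.613 to 19.9 TPM, and MMP14, a membrane-bound collagenase, from 75.1 to 272 TPM. TFPI2, a secreted inhibitor of serine proteases, rose from 579 ± 14.1 to 10437 ± 228 TPM. MMP1, TFPI2, TIMP1 and STC1, a secreted glycoprotein hormone, together made up 0.177% of the total in DMSO and 2.84% with the compound. SERPINB2, an inhibitor of plasminogen activators, rose from 0.79 to 117 TPM and ESM1, a secreted proteoglycan, from 17.8 to 329 TPM.

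Inflammatory genes rose. Of 21 tested cytokines and chemokines, 16 rose and 2 fell, with the same counts adjusted over the list alone (median log2 fold change 1.55, camera adjusted p = 7.61e-07, and adjusted p = 0.0676 with an estimated correlation). CXCL8, a neutrophil chemokine, was 41.4-fold higher, IL1B rose from 19.3 ± 1.08 to 413 ± 21.9 TPM and LIF from 21.4 to 105 TPM. CXCL12, a chemokine that stromal cells secrete, fell from 935 to 330 TPM. Of 19 genes that NF-κB induces, 15 rose and 1 fell, or 16 and 1 adjusted over the list alone (median log2 fold change 1.69, camera adjusted p = 4.3e-09, and adjusted p = 0.0922 with an estimated correlation). TRAF1 rose from 1.23 to 59.3 TPM, RELB, a subunit of NF-κB itself, from 4.79 to 46.8 TPM, TNFAIP3, its feedback inhibitor, from 11.1 to 68.2 TPM, and NFKBIA, which holds it in the cytoplasm, was 3.18-fold higher. BIRC3 and BCL2A1, inhibitors of cell death, were 28.1-fold and 22.5-fold higher. Of 37 interferon response genes, 23 rose and 3 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.00029, and adjusted p = 0.0798 with an estimated correlation). IFIT2 was 2.85-fold higher, whereas GBP1 fell from 85.8 to 29.6 TPM.

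Genes downstream of MAPK and protein kinase C rose in number. Of 32 immediate early and MAPK feedback genes, 24 rose and 5 fell (26 and 5 adjusted over the list alone), with camera adjusted p = 3.94e-07, and adjusted p = 0.0676 with an estimated correlation. SPRY2, a feedback inhibitor of receptor tyrosine kinase signalling, was 6.89-fold higher, PHLDA1 3.84-fold, IER3 2.85-fold and FOSL1, an AP-1 subunit, 2.54-fold. Of 28 genes on the protein kinase C list, PRKCA, PRKCD and PRKCE of the kinase itself included, 21 rose and 6 fell (21 and 7 adjusted over the list alone). The list had camera adjusted p = 2.92e-07, and adjusted p = 0.0676 with an estimated correlation. The members with the smallest adjusted p in limma were MMP1, TFPI2 and STC1, followed by MMP3 and CXCL8, which tied at 2.24e-10. STC1 rose from 132 to 1563 TPM. This list shares most of its members with the protease, cytokine and MAPK lists.

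The G2/M and mitosis list fell as a block: all 42 tested members were lower, also adjusted over the list alone, with a median log2 fold change of -1.01 (camera adjusted p = 7.17e-21, and adjusted p = 0.102 with an estimated correlation). CCNB1, the cyclin that drives entry into mitosis, fell from 614 ± 10.5 to 247 ± 7.56 TPM, CCNA2 from 151 to 48.4 TPM, CDC20, an activator of the anaphase-promoting complex, from 247 to 95.7 TPM, and KIF20A, a kinesin of cytokinesis, from 210 to 38.1 TPM. The 45 genes of G1/S and DNA replication went both ways, 10 higher and 15 lower, with the same counts adjusted over the list alone (camera adjusted p = 0.297, and adjusted p = 0.495 with an estimated correlation). CCND1, the G1 cyclin, was 1.7-fold higher, whereas TK1 was 1.93-fold and RRM2 1.64-fold lower. The mean log2 level of the G2/M list minus that of the G1/S list was 0.94 ± 0.03 in DMSO and -0.01 ± 0.05 with compound 11 (SD, n = 3 per group). An exact two-sided permutation test of this difference gave p = 0.1, the smallest that 3 against 3 libraries allow. CDKN1A, the p21 inhibitor of cyclin-dependent kinases, rose from 56.2 to 235 TPM; of the 27 p53 target genes, 9 rose and 6 fell, or 10 and 6 adjusted over the list alone (camera adjusted p = 0.389, and adjusted p = 0.495 with an estimated correlation).

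Genes known to respond to TGF-β through SMAD proteins did not move together. Of 30 tested, 10 rose and 15 fell, or 10 and 16 adjusted over the list alone (camera adjusted p = 0.0991, and adjusted p = 0.308 with an estimated correlation). TGFBI, COL1A1 and CCN2 fell, CCN2 from 410 to 216 TPM, while SMAD7, the inhibitory SMAD, rose 1.35-fold and SPHK1, sphingosine kinase, 2.28-fold. Of 22 TGF-β ligands, receptors and SMADs, 8 rose and 6 fell, or 8 and 7 adjusted over the list alone (camera adjusted p = 0.617, and adjusted p = 0.882 with an estimated correlation). TGFB2 fell from 107 to 21.2 TPM, TGFB1 was 1.12-fold lower, and TGFBR2 was 1.35-fold higher. The call of TGFB1 was lost in 6 of the settings tried, 4 of which left out 1 library. Of 24 YAP/TEAD target genes, 16 fell and 1 rose, with the same counts adjusted over the list alone (camera adjusted p = 3.9e-05, and adjusted p = 0.308 with an estimated correlation). The median log2 fold change of the YAP/TEAD list was -0.361, and 7 members did not pass, ANKRD1 and LATS2 among them (-0.04 and 0.17). Members with large changes were IGFBP3, which fell from 50.6 to 5.89 TPM, and F3, tissue factor, from 69.2 to 15.8 TPM, while NT5E rose 2.42-fold.

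Transcripts of the PI3K-AKT-mTOR pathway's own components changed in both directions. Of 47 tested, 15 rose and 10 fell, with the same counts adjusted over the list alone (median log2 fold change 0.07, camera adjusted p = 0.281, and adjusted p = 0.81 with an estimated correlation). Among all tested genes 25.3% rose and 24.3% fell, and the list did not stand out from the other genes in camera. PIK3CD and PIK3CA, catalytic subunits, were 1.76-fold and 1.64-fold higher, PIK3R3, a regulatory subunit, fell from 12.6 to 4.39 TPM, and AKT2 was 1.32-fold lower. AKT1 was at 160 TPM in DMSO and 153 TPM with the compound, MTOR at 45.9 and 50.6 TPM and PIK3R1 at 30.8 and 35.7 TPM, and none of these passed the threshold. AKT1 passed it only after the GC and length correction (log2 fold change -0.13), MTOR only without the 20 most abundant genes (0.16), and PIK3R1 only without compound 11 replicate 2 (0.31). RNA abundance does not measure the phosphorylation through which the pathway signals. Of 26 targets of FOXO transcription factors, which AKT phosphorylates, 18 rose and 4 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.000933, and adjusted p = 0.135 with an estimated correlation). SOD2 rose 3.9-fold, BCL6 2.46-fold, CITED2 2.34-fold and BTG1 2.05-fold, and SOD2 is also on the NF-κB list. The 4 that fell were IGF1R, BCL2L11, CDKN1B and TXNIP (log2 fold changes -0.48, -0.40, -0.38 and -0.32). Of 28 receptor tyrosine kinases and ligands upstream of PI3K, 12 rose and 13 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.981, and adjusted p = 0.987 with an estimated correlation). VEGFA rose 2.28-fold, while AXL fell 1.69-fold. Of 28 integrin and focal adhesion genes, 10 rose and 10 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.771, and adjusted p = 0.891 with an estimated correlation). ITGA2, a collagen receptor subunit, rose from 32.9 to 211 TPM, and CAV1, caveolin, fell from 530 to 125 TPM.

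Metabolic and housekeeping groups also shifted. Of 42 autophagy and lysosome genes, 35 rose and 2 fell, with the same counts adjusted over the list alone (median log2 fold change 0.43, camera adjusted p = 4.3e-09, and adjusted p = 0.0676 with an estimated correlation). NPC1, the lysosomal cholesterol exporter, rose from 51.2 to 182 TPM, SQSTM1, an autophagy receptor, from 361 to 1094 TPM, and the lysosomal protease CTSL 2.23-fold. Of 26 genes of cholesterol synthesis and uptake, 22 fell and 0 rose, or 24 and 0 adjusted over the list alone (median log2 fold change -0.44, camera adjusted p = 5.9e-08, and adjusted p = 0.0945 with an estimated correlation). MVK, mevalonate kinase, was 2.17-fold lower, ACAT2 1.83-fold, HMGCS1 1.72-fold and DHCR7, a late enzyme of the pathway, 1.56-fold. Of 21 heat shock genes, 14 fell and 1 rose, or 15 and 1 adjusted over the list alone (camera adjusted p = 0.000877, and adjusted p = 0.135 with an estimated correlation), led by DNAJB4, 2.96-fold lower, and HSPB1, 2.37-fold lower. Smaller falls were found in 44 nuclear genes of oxidative phosphorylation, where 19 fell and 2 rose, or 18 and 2 adjusted over the list alone (median log2 fold change -0.11, camera adjusted p = 0.021, and adjusted p = 0.316 with an estimated correlation). ATP5PB was 1.35-fold lower. The list lost its call under quantile normalization (camera adjusted p = 0.233), the GC and length correction (0.127) and without compound 11 replicate 3 (0.073). Of 33 genes of ribosome biogenesis, 15 fell and 3 rose, with the same counts adjusted over the list alone (camera adjusted p = 0.0305, and adjusted p = 0.25 with an estimated correlation). SRM, spermidine synthase, was 1.54-fold lower and ODC1, the first enzyme of polyamine synthesis, 2.57-fold higher; without compound 11 replicate 2 the list missed the threshold (camera adjusted p = 0.0635).

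**Figure D2:**
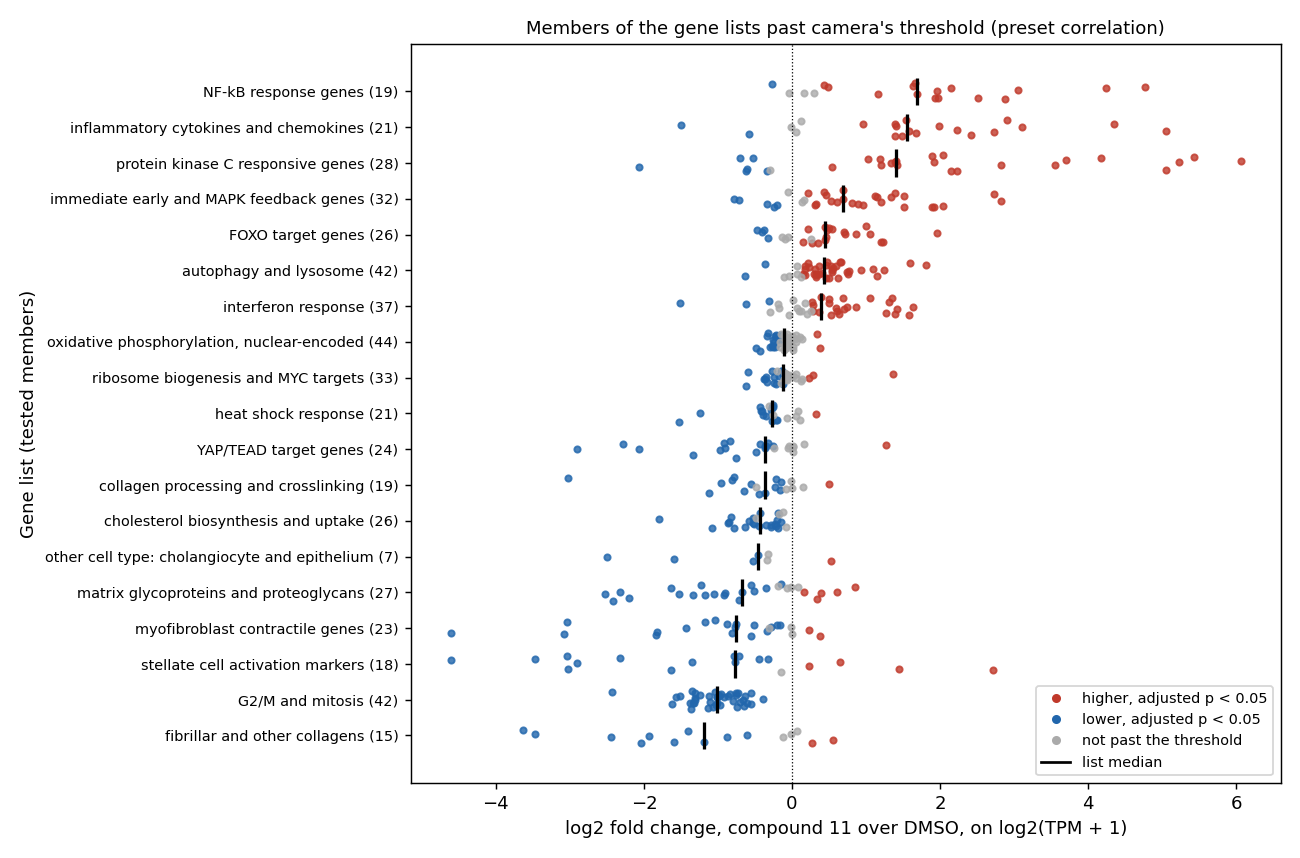
Each point is a tested member of 1 of the 19 gene lists past camera's threshold with the preset correlation; the horizontal axis is the log2 fold change of compound 11 over DMSO on log2(TPM + 1), colours mark members past an adjusted p of 0.05, and black bars are list medians. The 42 G2/M genes all lie below 0, and the medians of the collagen and NF-κB lists are -1.19 and 1.69.

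Markers of other liver cell types were mostly near the floor of detection. Among 7 tested genes of bile duct and other epithelia, 4 fell and 1 rose, or 6 and 1 adjusted over the list alone (camera adjusted p = 0.0288, and adjusted p = 0.172 with an estimated correlation). Those lower included KRT8, from 654 to 115 TPM, and KRT18, from 662 to 220 TPM, keratins that LX-2 cells themselves expressed in DMSO, and MUC1, from 3.51 to 2.29 TPM, while SOX9 rose 1.47-fold. With no filter the list missed the threshold (camera adjusted p = 0.175). Of 5 tested leukocyte markers, 3 rose and 0 fell, or 3 and 1 adjusted over the list alone (camera adjusted p = 0.402, and adjusted p = 0.519 with an estimated correlation): CD68, from 82.2 to 141 TPM, FCER1G, from 1.44 to 6.4 TPM, and CSF1R, from 3.24 to 5.09 TPM. These rose as the cytokine and NF-κB lists did, but so did 25.3% of all tested genes, so the shared direction shows no link. All 4 tested endothelial markers rose, with TIE1 going from 7.34 to 15.1 TPM and KDR from 1.11 to 4.57 TPM, and of 3 tested hepatocyte markers SERPINA1 and ASGR1 rose and CPS1 fell; both lists were too short for camera. ASGR1 missed the threshold without DMSO replicate 2 or compound 11 replicate 1 or 3. Of 13 mitochondrially encoded mRNAs, 6 rose and 0 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.0765, and adjusted p = 0.658 with an estimated correlation), and these mRNAs made up 4.68% to 4.85% of the total in DMSO and 4.78% to 5.31% with the compound. The mitochondrial list passed with no filter (camera adjusted p = 0.0342), without DMSO replicate 2 (0.0436), without compound 11 replicate 3 (0.00622) and after the GC and length correction (0.00158). Of 8 replication-dependent histone genes, whose RNAs lack a poly(A) tail, 1 rose and 2 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.777, and adjusted p = 0.874 with an estimated correlation).

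In all, 19 of 42 lists passed camera at the preset correlation, 7 higher and 12 lower. With the correlation estimated from these libraries 0 passed, the lowest adjusted p was 0.0676 and 14 lists had an unadjusted p under 0.05. The estimate for G2/M, 0.257, lay above the preset 0.01. Those for the autophagy, protein kinase C and interferon lists, -0.00162, -0.0329 and -0.0177, lay below it. Their adjusted p in camera still went from 4.3e-09, 2.92e-07 and 0.00029 to 0.0676, 0.0676 and 0.0798. A higher correlation between genes therefore cannot be what cost these 3 lists their calls. At an adjusted p of 0.05, fry, which asks whether a list's genes move one way without comparing them with other genes, called 37 of the 42.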

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

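The removal of the 20 most abundant genes and the GC and length correction were chosen after seeing the data; the other settings were fixed beforehand. The counts of genes past the threshold, in total, higher, lower and at 2-fold, stayed within 1.5 times of their values under every setting run. The total ranged from 5487 (mean of at least 5 TPM) to 6226 (replicate block) with all 6 libraries and from 5153 to 5472 with 1 library left out, and the count at 2-fold reached 939 at a pseudocount of 0.01. Rescaling to the same total changed nothing, since the totals were already equal. Of the main calls, 5536 were kept in direction and significance under quantile normalization, where 9 took the opposite sign. The number of lists past the threshold, 19, fell to 0 for camera with an estimated correlation and rose to 37 with fry, which tests another question; it was 18 to 20 with 1 library left out.

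Deviations of same-numbered libraries from their group means correlated at 0.0794, 0.149 and 0.0663, above the -0.103 to 0.0333 of differently numbered libraries. Not all of the same-numbered values were above 0.1, and the main model did not pair the samples by number. With the replicate number as a block, 6226 genes and 19 lists passed. Among the libraries of the other group, each library correlated best with the one of its own number, a hint from the data and not from the design.

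Of the named genes' values under the alternatives, 2995 kept their side of the threshold and direction, 12 lost a call, 6 gained one and 1 turned: AKT1, never past the threshold in either case, was at 0.0045 (log2) under quantile normalization. TGFB1 lost its call in 6 settings, with the adjusted p up to 0.102. Of the lists' values, 693 kept direction and side, 5 lost a call, 5 gained one and 9 turned in camera's direction, which compares a list with the other genes. All 9 were far from the threshold in both cases, and each median (log2) kept its sign. Receptor tyrosine kinases and ligands, at -0.144 in the main analysis, had -0.142 and -0.14 at pseudocounts of 0.1 and 0.01, -0.254 at a mean of at least 5 TPM, -0.193 without the 20 most abundant genes and -0.0888 without compound 11 replicate 2, with a range of -0.167 to 0.184 over the libraries left out. Xenobiotic metabolism went from -0.0187 to -0.0874 at a mean of at least 5 TPM, the ATF4 list from -0.000515 to -0.0161 under quantile normalization, and the histones from 0.0311 to 0.0688 without DMSO replicate 2 (range -0.0731 to 0.121 over the libraries left out) and 0.116 after the GC and length correction. The cause was not tested. Calls of oxidative phosphorylation, ribosome biogenesis and the epithelial list were those lost. The unknown depth limits what can be said of low genes.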

Other observations

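Several stress and metabolic groups had members that moved strongly in both directions, and as lists did not pass camera. Of 26 NRF2 targets, 13 rose and 8 fell, or 14 and 9 adjusted over the list alone (camera adjusted p = 0.239, and adjusted p = 0.348 with an estimated correlation); HMOX1, heme oxygenase, rose from 142 to 356 TPM and FTH1, ferritin heavy chain, from 5988 to 9413 TPM. Of 34 genes of the ATF4 response, 10 rose and 14 fell, the same counts adjusted over the list alone (adjusted p = 0.907, and adjusted p = 0.966 with an estimated correlation), with CEBPB 3.48-fold and PPP1R15A 3.01-fold higher and CHAC1 and SLC7A5, chosen after their values were seen, at log2 fold changes of -1.27 and -0.87. Chaperones of the unfolded protein response split 7 and 7 of 24, also adjusted over the list alone (adjusted p = 0.801, and adjusted p = 0.932 with an estimated correlation), with EDEM1 2.43-fold higher and CREB3L2 1.77-fold lower. Of 32 hypoxia and glycolysis genes, 18 rose and 12 fell, or 19 and 12 adjusted over the list alone (adjusted p = 0.227, and adjusted p = 0.502 with an estimated correlation), with SLC2A3, a glucose transporter, 2.5-fold higher and PFKP 1.58-fold lower. Of 32 apoptosis regulators, 12 rose and 9 fell, the same counts adjusted over the list alone (adjusted p = 0.227, and adjusted p = 0.519 with an estimated correlation), with MCL1 1.65-fold higher and BIRC5, which also belongs to the G2/M list, 2.06-fold lower.

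Lipid genes were split as well. Of 27 genes of fatty acid synthesis and storage, 5 rose and 10 fell, or 5 and 11 adjusted over the list alone (camera adjusted p = 0.215, and adjusted p = 0.308 with an estimated correlation); SCD, the stearoyl-CoA desaturase, fell from 500 to 215 TPM. Of 20 genes of fatty acid oxidation, 7 rose and 3 fell, the same adjusted over the list alone (adjusted p = 0.22, and adjusted p = 0.519 with an estimated correlation), with ANGPTL4 6.86-fold and CPT1A 1.49-fold higher. Genes of quiescent stellate cells did not rise as a list: 3 of 14 rose and 3 fell, the same adjusted over the list alone (adjusted p = 0.928, and adjusted p = 0.951 with an estimated correlation), with PLIN2, a lipid droplet protein, 1.42-fold higher and GATA4 1.63-fold lower. Of 14 glucocorticoid-responsive genes, 8 rose and 4 fell (adjusted p = 0.261, and adjusted p = 0.398 with an estimated correlation), of 16 xenobiotic genes 3 rose and 2 fell (adjusted p = 0.837, and adjusted p = 0.882 with an estimated correlation), of 9 metal-responsive genes 2 rose and 5 fell (adjusted p = 0.355, and adjusted p = 0.495 with an estimated correlation), each with the same counts adjusted over the list alone. HSD11B1, which regenerates cortisol, rose from 0.262 to 9.09 TPM and CYP1A1 from 4.02 to 20.2 TPM. Of 77 cytosolic ribosomal protein genes, 6 rose and 20 fell, or 5 and 18 adjusted over the list alone (adjusted p = 0.219, and adjusted p = 0.879 with an estimated correlation), with RPS26 1.51-fold lower. Median, mean and camera's direction differed in sign for the receptor tyrosine kinase, integrin, xenobiotic, histone, TGF-β ligand and ATF4 lists, which were all far from the threshold.

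All of the tests that follow were chosen after the result they bear on, or values close to it, had been seen. The first pattern is the breadth of the response, 5984 of 12067 tested genes. Removing the 20 most abundant genes and rescaling left 5988 genes past the threshold. Those genes took 11.64% to 11.89% of the total in DMSO and 13.15% to 13.66% with the compound. With shares so close, the count could hardly have come out otherwise. It is this small change in share, not the count, that argues against these genes as the whole cause. Correcting each library for GC content and transcript length left 6164, which argues against such a bias as the whole cause. There are only 10 splits of the 6 libraries into 3 and 3, too few for a share under 0.05. The real split, 1 of the 10, gave 5984 genes past the threshold in limma. The highest of the others gave 0, with 94 to 192 genes at an unadjusted p under 0.05. Each of the others mixes the treatments, so the difference between treatments widens the spread within its groups. Few calls were thus built into them, and no conclusion about chance is drawn from the 0. For the gene lists the real split, again 1 of 10, gave 19 past camera's threshold and the highest of the others 14; each of those splits still sets 2 libraries of a treatment against 1, and this too asks for caution with the preset correlation.

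The second pattern is the joint fall of collagen, matrix and contractile genes, 59 of 84 tested members of the 4 lists, with 10 higher. With the 20 most abundant genes removed, FN1 of the 4 lists among them, the median log2 fold change was -0.563 against -0.584 before. This result could hardly have come out otherwise. The removed genes took 11.64% to 11.89% of the total in DMSO and 13.15% to 13.66% with the compound. Without them the median of all tested genes moved only from -0.0013 to 0.0246. So small a change in their share cannot account for the fall. A general loss of SMAD-driven transcription is a candidate explanation, since all samples received TGF-β1. Of the 25 tested TGF-β/SMAD targets outside those 4 lists, 44% (11) fell, against 24.3% of all tested genes, and 36% (9) rose, against 25.3%. Both shares lie above those of all genes, so such a loss is neither excluded nor borne out, and whether these genes respond to TGF-β1 in these cells could not be tested without untreated libraries.

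The third pattern is the rise of cytokine and NF-κB target genes and of some proteases, such as MMP1; the protease list as a whole did not pass camera. Leukocytes in the compound 11 samples would have brought their abundant transcripts. The 18 leukocyte markers fixed beforehand, CD68 included, summed to 92.8 ± 1.77 TPM in DMSO and 157 ± 7.02 TPM with the compound (SD, n = 3 per group), a rise equal to 16.4% of that of IL1B alone, while LYZ stood at 2.63 and 1.82 TPM, TYROBP at 0.47 and 0.348 TPM and PTPRC at 0.236 and 0.324 TPM. FCER1G went from 1.44 to 6.4 TPM, CSF1R from 3.24 to 5.09 TPM and ITGAM from 0.0697 to 0.289 TPM, but the small rise of the sum argues against such cells as the whole cause. A response through protein kinase C may underlie the pattern, as a hypothesis. Of the 7 tested members of that list found on no other tested list, 57.1% (4) rose and 2 fell. Among all tested genes 25.3% rose and 24.3% fell. SERPINB2, TFPI2, STC1 and PRKCD rose, PRKCA and RCAN1 fell and PRKCE did not pass. PRKCA, PRKCD and PRKCE are protein kinase C genes themselves, so their levels need not follow its activity. The share does not tell protein kinase C from NF-κB or MAPK signalling in general.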
